A study of Homo sapiens with 24 samples.

How the data were processed

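RNA of cells given as the U2932 line in 20 of 24 cell line entries, and in the treatment text of all, was sequenced, per the labels after Qiagen RNeasy extraction and TruSeq stranded library preparation, on a NextSeq 500. The labels name both total RNA and mRNA kits without saying which libraries used which. They give 6 PBS control, 4 PNA2 and 4 siRNA libraries at 48 h, and 5 control and 5 PNA2 libraries at 72 h. The extraction text names 48 h alone for every library, against the titles and time entries of the 72 h libraries, which were followed here, so the later time is in some doubt. The PNA2 dose is printed as the labels write it, 8 mM, and its unit is doubtful. Per the submitters' processing notes, Trimmomatic, HISAT2 2.2.1, SAMtools 1.7, HTSeq 0.11.0 and DESeq2 were used with GRCh38. The notes do not state whether strand was used in counting, so a gene that overlaps another on the opposite strand is uncertain.

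The 72 h table holds normalized signal that the authors made by dividing read counts by a size factor per library, as deposited. Multiplying back gave whole reads in 100% of values within 0.01. It covers 19836 genes, each given as protein-coding in the table itself. The size factors ran from 0.73 to 1.187.

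The 48 h table holds values of another unit, which the authors made by adjusting read counts per gene and batch, as deposited, without division by depth. It covers 61541 genes, of which 21877 had values that were not whole and 39664 were whole in every library. Values below 0 occurred in 5099 genes, with a lowest value of -223.8. The batches are not named in the labels and were read from ties. Among 6826 genes with low values, pairs of libraries within a batch had equal values in 25.3% to 40.6% of genes, and pairs between batches in 0%. Batch A held 9 libraries (controls 1, 2 and 4, PNA2 1 and 2, siRNA 1 to 4) and batch B held 5 (control 3, the unnumbered controls, PNA2 3 and 4). The 2 control columns that share one header are called unnumbered controls 6 and 7 after their column. The adjustment made the mean of all libraries of a batch nearly equal (median difference 3.32% of the gene mean over 8251 genes, SD 4.39). All siRNA libraries are in batch A, so part of the siRNA effect was moved into the controls. The SD of the siRNA log2 difference was 0.298 against batch A controls and 0.195 against batch B controls. Induced genes with low values therefore have inflated folds in siRNA, and the change with the batches aligned on their controls is printed beside them.

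Gene symbols were taken from the deposited tables. Gene types, positions and transcript lengths came from GENCODE 29, which holds 58366 of the 48 h and 19804 of the 72 h gene ids. Some deposited 48 h symbols were altered, such as BOP 1.00, read as BOP1, and PES 1.00, read as PES1. Those genes were not matched to their lists at 48 h. At 48 h values below 0 were set to 0, divided by a library scale from TMM (edgeR 4.0.16), and transformed as log2 of the value plus 1. A limma 3.58.1 model with a mean-variance trend was fitted in R 4.3.3 with group and batch. At 72 h the same model was fitted with group alone to log2 of the deposited value plus 1. Genes were kept with a value of 10 or more in at least 4 libraries at 48 h or 5 at 72 h. The p values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 and no fold minimum. The design written before the data were examined had no batch term and no rescaling at 48 h. The batch term and TMM scaling became the main choice after the batches and the missing depth scaling were seen, and the design as first written is kept as an alternative.

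The 27 gene lists were fixed before the data were examined: MYC network, MYC-activated, MYC-repressed, ribosome biogenesis, ribosomal proteins, nucleotide and polyamine synthesis, glycolysis, G1/S, G2/M, p53 targets, apoptosis regulators, interferon, integrated stress response, unfolded protein response, heat shock, NF-kB targets, cholesterol synthesis, lysosome and autophagy, oxidative phosphorylation, mitochondrial genome, replication histones, B cell identity, germinal centre and plasma cell, and markers of T and NK cells, myeloid cells, erythroid and megakaryocyte cells, and stroma and epithelium. Lists with at least 3 genes tested were tested with camera (limma) against all other genes at a preset correlation of 0.01, adjusted over the lists of a comparison, and with an estimated correlation. The rotation test fry, which asks whether a list's genes move one way and does not compare them with other genes, was run beside camera and decided no call. Counts of list members use the adjustment over all genes, and counts adjusted over the list alone are given beside them.

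The rule for naming genes was fixed before the data were examined. It names MYC, and of called genes with a mean value of 100 or more in at least one group, the 6 largest increases and 6 largest decreases whose groups did not overlap. For each list called by camera it also names the 3 members with the smallest p in the list's direction, or 2 where more than 6 lists were called. Some genes are not reported here, and counts of genes include them. Overlap was judged on the tested log2 values with the fitted batch difference removed. Group means and SDs of single genes are of deposited values, and log2 changes are of the fit, so the means need not give the same ratio. MYC and the mitochondrial share of each library were also tested with exact two-sided permutation tests.

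The steps were tested on simulated data with 200 genes changed by known folds and the batch adjustment imitated with sva 3.50.0. For PNA2 at 48 h, 2-fold changes were found in 71.4% (higher) and 80% (lower) of cases and 4-fold changes in 90.9% and 91.4%, with 6 false calls (3.4% of calls). For siRNA the shares were 74.2% and 78.9% at 2-fold and 97.6% and 78.4% at 4-fold, with 12 false calls (6.7%), and the median estimates for a log2 change of 2 were 2.13 and -1.46. For 72 h they were 83.7% and 68% at 2-fold and 92% and 97.1% at 4-fold, with 15 false calls (7.9%). Changes of 1.5-fold were found less often, in 40.6% and 60% for PNA2 at 48 h. They were found in 51.9% and 52.2% for siRNA and 56.2% and 62.2% at 72 h. With the real data the median SE of a log2 change was 0.119 for PNA2 and 0.133 for siRNA at 48 h, and 0.128 at 72 h.

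The comparisons were PNA2 against control and siRNA against control at 48 h, PNA2 against siRNA at 48 h, and PNA2 against control at 72 h, each within its table. Alternatives chosen before the data were examined were pseudocounts of 0.5 and 5, no filter and a filter at 50, other scalings, quantile normalization, no trend, a replicate block, only the 2 groups compared, a fold minimum, leaving out each library, and edgeR and DESeq2 1.42.0 on the recovered 72 h reads. Alternatives chosen after the data were seen were no batch term, the design as first written, batches aligned on their controls, each batch alone, and removal of a trend with transcript length. Overlap of calls that share controls was set beside 100 simulated draws of unchanged groups. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures. Levels were not compared between the tables, which were normalized apart. Every column of values was used, and reads were not analysed here.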

Results

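RNA-seq was performed on cells given as U2932, a human diffuse large B-cell lymphoma line, to follow transcript levels after nucleic acid reagents directed at MYC. One reagent, PNA2, is a gamma peptide nucleic acid, a synthetic nucleic acid analogue with a peptide-like backbone, given at a labelled dose of 8 mM. The other was an siRNA at 500 nM, delivered by electroporation. The 24 libraries comprised 6 PBS controls, 4 PNA2 and 4 siRNA libraries at 48 h, and 5 controls and 5 PNA2 libraries at 72 h. The labels did not say whether replicates were separate cultures and named no electroporated control, so siRNA comparisons hold the electroporation effect too. The cell line entries of the 4 siRNA libraries differed from U2932 and from one another in the last digit, while their treatment text named U2932.

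The 48 h values summed to 11.12 M to 14.46 M per library in the controls, 14.88 M to 16.03 M in PNA2 and 12.63 M to 16.17 M in siRNA. Tied values gave batch A, with 3 controls, 2 PNA2 and 4 siRNA libraries, and batch B, with 3 controls and 2 PNA2. At 72 h the whole reads recovered came to 8.22 M to 13.28 M in the controls and 11.25 M to 13.69 M in PNA2. The 10 most abundant genes took 5.00% ± 0.175 (SD, n = 6), 6.49% ± 0.503 (n = 4) and 5.12% ± 0.0925 (n = 4) of the control, PNA2 and siRNA totals at 48 h. At 72 h they took 5.10% ± 0.259 (n = 5) of the control totals and 7.98% ± 0.835 (n = 5) of the PNA2 totals.

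MYC (ENSG00000136997, GRCh38 chromosome 8, 127735434 to 127741434, forward strand) encodes a transcription factor that promotes growth and ribosome production, and was the target of both reagents. At 48 h its deposited value was 7051, 5926, 4712 and 6297 in control replicates 1 to 4 and 7083 and 5914 in the unnumbered controls. It was 7536, 7923, 8045 and 9687 in PNA2 replicates 1 to 4, and 4252, 3931, 3861 and 4244 in siRNA replicates 1 to 4. The group means were 6164 ± 880 (SD, n = 6), 8298 ± 951 (n = 4) and 4072 ± 205 (n = 4). All 4 PNA2 libraries lay above all 6 controls before rescaling, but their totals were higher as well. Scaled by TMM the groups overlapped, with PNA2 replicates 1 and 2 (7198 and 7260) below control replicate 2 (7721). In neither form were the PNA2 libraries lower as a group. They went against the label of a MYC knockdown and are called the libraries labelled PNA2 below. At 72 h MYC stood at 1121, 2321, 2035, 2845 and 826.4 in control replicates 1 to 5, a mean of 1830 ± 840 (SD, n = 5). It stood at 2007, 2032, 459.9, 1966 and 1809 in PNA2 replicates 1 to 5, a mean of 1655 ± 674 (n = 5).

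In the siRNA libraries MYC fell by 0.82 on the log2 scale (SE 0.11, 95% CI -1.06 to -0.59, limma adjusted p = 0.000396), and by a log2 change of -0.89 in batch A, the only batch with siRNA libraries. An exact two-sided permutation test over 210 arrangements gave p = 0.00476, and within batch A p = 0.0286 over 35, the smallest possible. In the libraries labelled PNA2 at 48 h MYC was not lower than in the controls, with a log2 fold change of 0.24 (SE 0.10, 95% CI 0.03 to 0.45, adjusted p = 0.114). The change was 0.01 in batch A (adjusted p = 0.941) and 0.47 in batch B (adjusted p = 0.00964), and the exact two-sided p was 0.0714 over 210 arrangements and 0.1 over the 100 within batches. Without PNA2 replicate 2 the change was 0.29 (adjusted p = 0.0432, range over the alternatives 0.00964 to 0.941). At 72 h the change was -0.18 (SE 0.45, 95% CI -1.15 to 0.79, adjusted p = 0.794; exact two-sided p = 0.706 over 252 arrangements). It was 0.02 without control replicate 4 and 0.24 without PNA2 replicate 3, so no direction is given for 72 h.

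**Figure D1:**
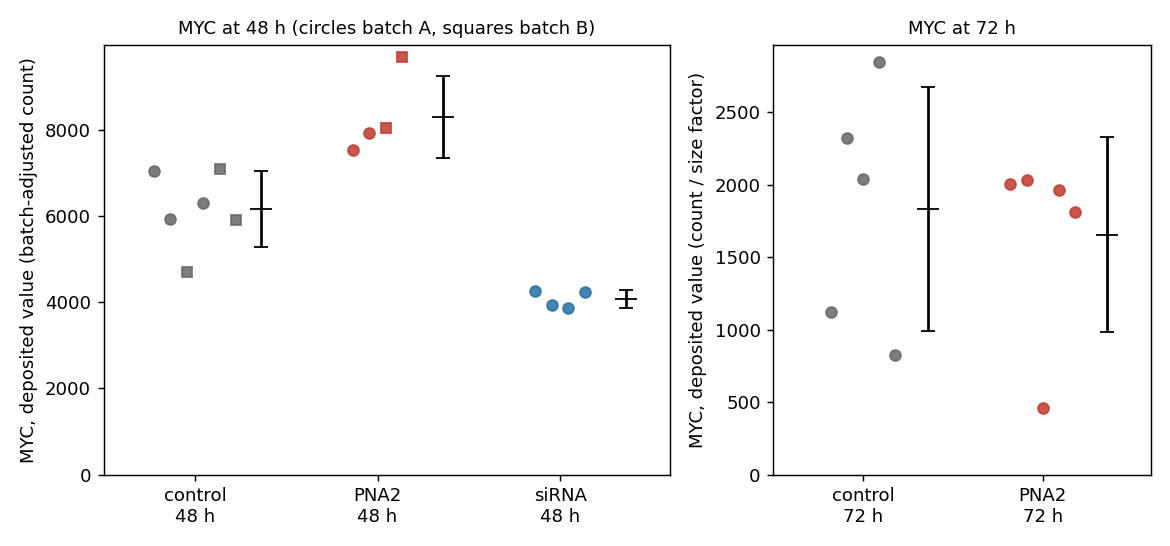
Deposited MYC value in each library at 48 h (circles batch A, squares batch B) and at 72 h, with the group mean and SD as black bars. At 48 h the siRNA libraries lie at 3861 to 4252, below all controls, and the libraries labelled PNA2 at 7536 to 9687, above all controls. The 48 h values are not scaled for depth, and once scaled the PNA2 and control libraries overlap.

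The comparison of PNA2 with PBS at 48 h asked how transcripts differed after the peptide nucleic acid. Transcripts of the mitochondrial genome, which encodes subunits of the respiratory chain, were higher. They took 5.36% ± 0.571 (SD, n = 4) of the totals in the libraries labelled PNA2 and 2.41% ± 0.571 (n = 6) in the controls, with no overlap (exact two-sided permutation p = 0.00476 over 210 arrangements, adjusted over 3 comparisons p = 0.0119). MT-ND1, a subunit of complex I, rose to 61400 ± 5480 (SD, n = 4) from 18100 ± 7060 (n = 6), a log2 change of 1.66 (SE 0.21, adjusted p = 0.000262). Group means of single genes, here and below, are of deposited values. The log2 changes come from the fit, at 48 h with scaling and a batch term, so they can differ from the ratio of those means. MT-RNR2, the large mitochondrial ribosomal RNA, rose by 1.63 (SE 0.24, adjusted p = 0.000664), by 2.19 in batch A and 1.06 in batch B. Of 13 protein-coding mitochondrial genes, 11 were higher and 0 lower (12 higher when adjusted over the list alone). The list's mean log2 change was 1.29 (camera adjusted p = 1.13e-11, adjusted p = 0.472 with an estimated correlation), 1.16 within batch A and 1.44 within batch B.

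**Figure D2:**
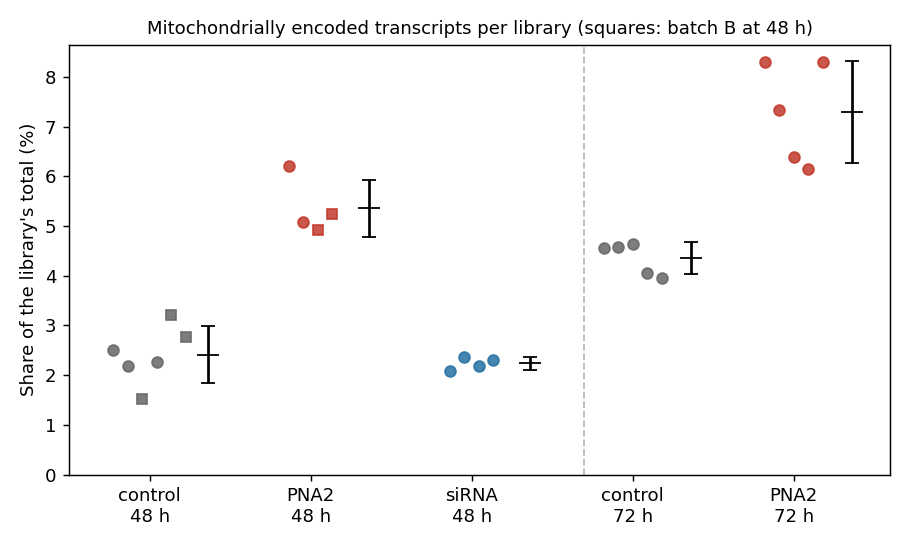
Share of each library's total taken by transcripts of the mitochondrial genome, in percent, by group and time, with group mean and SD (squares are batch B at 48 h). The libraries labelled PNA2 lie at 4.93% to 6.20% at 48 h and at 6.15% to 8.30% at 72 h, above every control of the same time.

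Cytoplasmic ribosomal protein transcripts were higher as well in the libraries labelled PNA2 at 48 h. RPL27, of the large ribosomal subunit, stood at 13800 ± 1270 (SD, n = 4) against 7570 ± 1130 (n = 6), a log2 change of 0.68 (SE 0.07, adjusted p = 7.78e-05), and RPL34 changed by 0.76 (SE 0.08, adjusted p = 7.78e-05). Of 67 genes tested, 58 were higher and 1, RPS10, was lower (61 and 1 when adjusted over the list alone). The mean log2 change was 0.44 (camera adjusted p = 3.16e-32, adjusted p = 0.472 with an estimated correlation), 0.39 within batch A and 0.50 within batch B. Ribosomal protein genes have many processed pseudogenes, which makes single members uncertain.

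Further genes with large increases at 48 h were TTN, encoding the sarcomere protein titin, and SH2D2A, encoding an adaptor in T cell signalling. TTN rose to 1370 ± 333 (SD, n = 4) from 273 ± 46.5 (n = 6), a log2 change of 2.11 (SE 0.14, adjusted p = 9.68e-07; 1.94 in batch A, 2.29 in batch B). SH2D2A rose by 1.73 (SE 0.18, adjusted p = 6.99e-05). IFITM2, an interferon-induced membrane protein with near-identical neighbours, rose by 1.54 (SE 0.20, adjusted p = 0.000272). SNORD3A, a small nucleolar RNA with several near-identical copies, had deposited means of 279 ± 92.8 and 7.43 ± 13.5, and its log2 change of 5.85 (SE 0.87, adjusted p = 0.000664) rests on controls near 0. TTN and its antisense neighbours share reads if strand was not used in counting, which the sources used here do not state.

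Among the largest decreases at 48 h was HBEGF, a growth factor that binds the EGF receptor, which fell to 272 ± 141 (SD, n = 4) from 591 ± 76.2 (n = 6), a log2 change of -1.46 (SE 0.25, adjusted p = 0.00164; -1.53 in batch A, -1.38 in batch B). IGKJ4, a joining segment of the immunoglobulin kappa locus, changed by -1.74 (SE 0.27, adjusted p = 0.00106) and AMN, encoding the amnionless protein, by -1.23 (SE 0.15, adjusted p = 0.000178; -0.71 in batch A, -1.75 in batch B). NPTX1, encoding a neuronal pentraxin, changed by -1.30 (SE 0.19, adjusted p = 0.000514) and by -3.97 with the batches aligned on their controls. LTB, encoding lymphotoxin beta, changed by -2.55 (SE 0.82, adjusted p = 0.0454; -4.63 in batch A, -0.46 in batch B). In PNA2 replicate 2 it lay at the floor of 0, and without that library it changed by -1.03 (adjusted p = 0.0033). MIR3142HG, the host transcript of a microRNA, changed by -1.67 (SE 0.43, adjusted p = 0.016; -3.08 in batch A, -0.25 in batch B) and by -1.02 without PNA2 replicate 2. Its call was lost without the batch term (adjusted p = 0.0537), also not rescaled (0.0503), with only the 2 groups compared (0.0548) and within batch B (0.158), with a range over the alternatives of 0.00422 to 0.158. The LTB call was lost without control replicate 1 (adjusted p = 0.0935), 2 (0.0936), 3 (0.0564) or 4 (0.0825), and over the alternatives its adjusted p ran from 0.0033 to 0.168.

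Genes controlled by NF-kB and heat shock genes were lower in the libraries labelled PNA2. In a list of NF-kB targets 10 of 22 genes were lower and 0 higher (15 lower and 1 higher when adjusted over the list alone), with a mean log2 change of -0.30 (camera adjusted p = 0.000303, adjusted p = 0.507 with an estimated correlation; -0.40 within batch A, -0.20 within batch B). ICAM1, an adhesion molecule, changed by -0.76 (SE 0.13, adjusted p = 0.00164; -1.17 in batch A, -0.34 in batch B) and TNFAIP3, an inhibitor of NF-kB, by -0.79 (SE 0.14, adjusted p = 0.00242; -1.08 in batch A, -0.49 in batch B). The ICAM1 call was lost with no batch term and no rescaling (-0.56, adjusted p = 0.0792, range over the alternatives 0.00062 to 0.0792). Of 13 heat shock genes 5 were lower (8 adjusted over the list alone), namely CHORDC1, HSPH1, HSP90AB1, AHSA1 and HSPA8, and 0 higher. Their mean log2 change was -0.24 (camera adjusted p = 0.00175, adjusted p = 0.507 with an estimated correlation), -0.30 within batch A and -0.17 within batch B. CHORDC1, an HSP90 co-chaperone, changed by -0.70 (SE 0.10, adjusted p = 0.000457) and HSPH1 by -0.51 (SE 0.09, adjusted p = 0.00182).

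In a list of germinal centre and plasma cell genes 4 of 22 were lower and 0 higher, with the same 4 when adjusted over the list alone. Among them were MME, ASB13 and IRF4, a transcription factor of activated B cells. IRF4 changed by -0.55 (SE 0.07, adjusted p = 0.000205) and ASB13 by -0.69 (SE 0.11, adjusted p = 0.000852). The list's mean was -0.28 (camera adjusted p = 0.00225, adjusted p = 0.688 with an estimated correlation). Within batch A it was -0.23 and did not pass (camera adjusted p = 0.275, range over the alternatives 3.29e-08 to 0.275), and within batch B it was -0.32. Without PNA2 replicate 1 the mean was -0.45, and without replicate 2 it was -0.12.

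Other lists moved mainly in 1 library, replicate 2 of the libraries labelled PNA2. Genes of the integrated stress response, which slows translation under stress, had a mean log2 change of 0.69 (camera adjusted p = 0.000682, adjusted p = 0.688 with an estimated correlation) with 2 of 24 genes higher and 0 lower (2 adjusted over the list alone). The mean was 0.15 without PNA2 replicate 2 (camera adjusted p = 0.648) and 1.44 and -0.049 within batches A and B, so the rise did not hold within batch B. PCK2, which makes phosphoenolpyruvate in mitochondria, changed by 0.93 (SE 0.27, adjusted p = 0.0302) and by 0.45 without that library, and DDIT4, an inhibitor of mTOR, by 0.59 (SE 0.17, adjusted p = 0.0321). The DDIT4 call was lost without PNA2 replicate 2 (0.34, adjusted p = 0.0598), 3 (0.0554) or 4 (0.0555) or control replicate 1 (0.0671) or 3 (0.0646). The PCK2 call was lost without control replicate 1 (adjusted p = 0.0586), 2 (0.0658) or 4 (0.0527). Over the alternatives the adjusted p ran from 0.00338 to 0.0872 for DDIT4 and from 0.0079 to 0.0937 for PCK2.

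**Figure D3:**
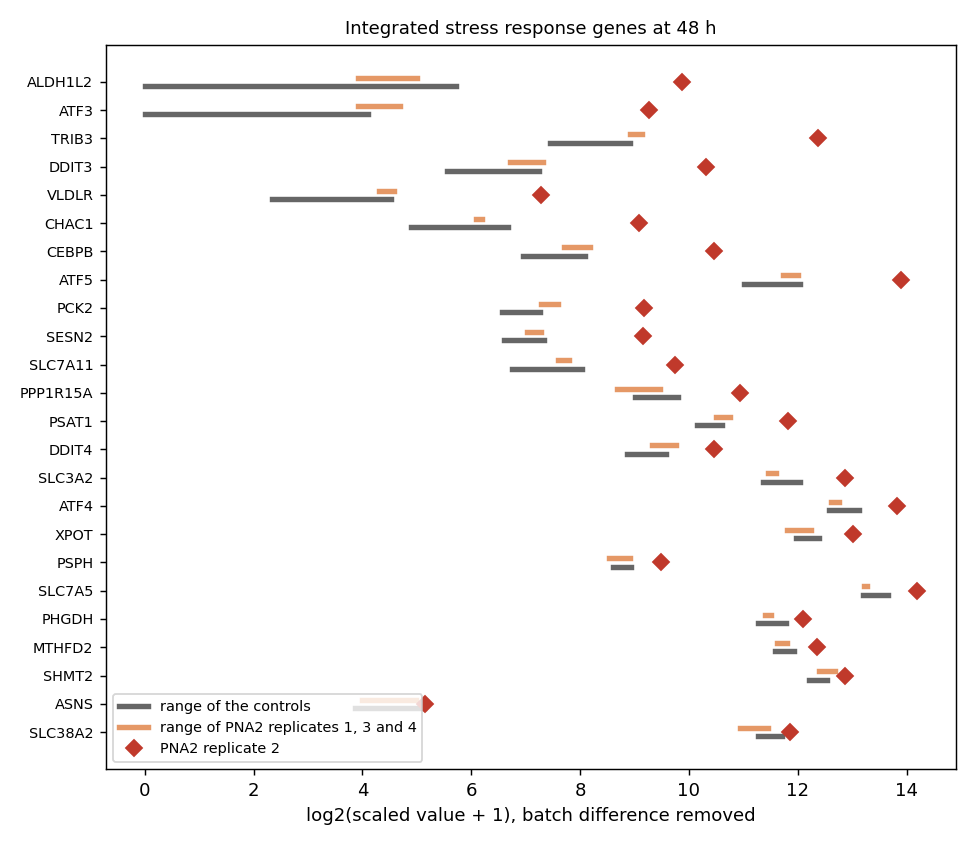
Values of 24 integrated stress response genes at 48 h (log2 of the scaled value, batch difference removed) as the range of the controls, the range of PNA2 replicates 1, 3 and 4, and PNA2 replicate 2 as diamonds. TRIB3 lies at 12.38 in PNA2 replicate 2, at 8.91 to 9.13 in the other libraries labelled PNA2 and at 7.44 to 8.92 in the controls.

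The lysosome and autophagy list had a mean log2 change of 0.25 (camera adjusted p = 0.002, adjusted p = 0.688 with an estimated correlation), with 3 of 27 genes higher and 0 lower (2 adjusted over the list alone). They were MAP1LC3B, PSAP and CTSB, of which the lysosomal proteins PSAP and CTSB changed by 0.59 (SE 0.13, adjusted p = 0.00864) and 0.50 (SE 0.12, adjusted p = 0.0105). The list's mean was 0.029 and PSAP's change 0.39 without PNA2 replicate 2, and the list's mean was 0.006 within batch B. Interferon-induced genes had a mean of 0.44 (camera adjusted p = 0.002, adjusted p = 0.688 with an estimated correlation), with 7 of 27 higher and 1, IFIH1, lower (9 and 2 adjusted over the list alone). IFIT5, an RNA sensor, changed by 0.99 (SE 0.18, adjusted p = 0.00216) and IFITM3 by 1.46 (SE 0.32, adjusted p = 0.00717). Their list mean was 0.27 without PNA2 replicate 2 (camera adjusted p = 0.175), 0.71 within batch A and 0.099 within batch B (camera adjusted p = 0.765).

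MYC-activated genes, many of them in ribosome assembly, were lower in the pooled test in the libraries labelled PNA2, although MYC itself was not. Of 53 genes 11 were lower and 0 higher (12 adjusted over the list alone), with a mean log2 change of -0.19 (camera adjusted p = 2.37e-05, adjusted p = 0.688 with an estimated correlation). The mean was -0.39 within batch A, 0.011 within batch B and -0.087 without PNA2 replicate 2, so the direction did not hold within batch B. When the libraries were not rescaled it was 0.007, moved with the median of all genes (by 0.19), which says nothing of this list. PLK1, a mitotic kinase, changed by -0.32 (SE 0.06, adjusted p = 0.00398) and PPAN, of ribosome assembly, by -0.46 (SE 0.11, adjusted p = 0.00952). Ribosome biogenesis genes had a mean of -0.17 (camera adjusted p = 0.002, adjusted p = 0.688 with an estimated correlation), with 0 of the 29 matched genes called by limma, also adjusted over the list alone, and 8 at unadjusted p below 0.05. BOP1, of this list, and PES1, of the MYC-activated list, were not matched by symbol and are not counted. Both were called lower (-0.47 and -0.31). TSR1 (-0.33, adjusted p = 0.0632) and GAR1 (-0.37, adjusted p = 0.0656) were called without control replicate 3 (-0.38 and -0.44), TSR1 also without PNA2 replicate 1 (-0.39) and GAR1 without PNA2 replicate 4 (-0.49). Their adjusted p ran over the alternatives from 0.0329 to 0.578 and from 0.0271 to 0.701. The list's mean was -0.029 without PNA2 replicate 2 and 0.093 within batch B, and not rescaled it moved with all genes to 0.03.

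Cell cycle and nucleotide synthesis genes likewise followed 1 library. The G1/S list had a mean log2 change of -0.22 (camera adjusted p = 0.00101, adjusted p = 0.688 with an estimated correlation), with 8 of 30 lower and 1, CCND2, higher (11 and 1 adjusted over the list alone). UHRF1, which maintains DNA methylation, changed by -0.58 (SE 0.11, adjusted p = 0.00243) and the cyclin CCNE1 by -0.63 (adjusted p = 0.00542). The CCNE1 call was lost with a replicate block (-0.57, adjusted p = 0.0554) and when not rescaled (-0.43, 0.0536). The G2/M list had a mean of -0.14 (camera adjusted p = 0.0116, adjusted p = 0.688 with an estimated correlation), with 2 of 31 lower and 0 higher (1 adjusted over the list alone), the phosphatase CDC25B (-0.51, adjusted p = 0.00281) and the checkpoint kinase BUB1B (-0.29, adjusted p = 0.0374). The nucleotide and polyamine synthesis list had a mean of -0.16 (camera adjusted p = 0.0196, adjusted p = 0.688 with an estimated correlation), with 2 of 23 lower and 0 higher (1 adjusted over the list alone), the purine enzyme ADSL (-0.73, adjusted p = 0.00479) and CTP synthase CTPS1 (-0.36, adjusted p = 0.0358). Without PNA2 replicate 2 these 3 means were -0.031, -0.036 and 0.009, and within batch B they were -0.031, -0.066 and 0.051. When not rescaled the G2/M and nucleotide means moved with all genes to 0.053 and 0.041, and both calls were lost (camera adjusted p = 0.114 each). Both were also lost under quantile normalization, where G2/M was -0.114 (0.0768) and nucleotide synthesis -0.128 (0.0755). The ADSL call was lost with a replicate block (-0.72, adjusted p = 0.0538) and the CDC25B call when not rescaled (-0.32, 0.0834).

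Leaving out other libraries also moved these lists. The nucleotide list's call was lost without control replicate 1 (-0.13, camera adjusted p = 0.058) or 2 (-0.13, camera adjusted p = 0.0866), and the G2/M mean was -0.22 without PNA2 replicate 1. The CTPS1 call was lost without control replicate 1 (adjusted p = 0.0795), 2 (0.0791), 4 (0.0706) or unnumbered control 6 (0.0543), and its change was -0.19 without PNA2 replicate 2. The BUB1B call was lost without control replicate 1 (adjusted p = 0.0809), 2 (0.0795), 4 (0.0647), unnumbered control 7 (0.0535), PNA2 replicate 2 (-0.16, 0.0706) or 3 (0.0714). Over the alternatives the adjusted p ran from 0.0221 to 0.492 for CTPS1 and from 0.0193 to 0.626 for BUB1B.

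The remaining lists did not pass camera in the libraries labelled PNA2 at 48 h. Among MYC-network genes 1 of 11, MGA, was higher (camera adjusted p = 0.353), and among MYC-repressed genes SESN3, BTG1 and TXNIP were higher and CDKN1C and GADD45A lower (0.637). In glycolysis PFKM, PFKP and PGAM1 were lower (0.268), among p53 targets BBC3 and RPS27L were higher (0.637), and in the unfolded protein response HYOU1 and CALR were lower (0.353). Among apoptosis regulators BCL2L2, CASP9 and BCL2L11 were higher and BCL2L1 and TNFRSF10A lower (0.637). In cholesterol synthesis SREBF2 was higher and EBP, LSS and MVD lower (0.143), in nuclear-encoded oxidative phosphorylation NDUFA4 and COX7B were higher (0.516), and of the replication histones H2AC11 was higher (0.38). In B cell identity CD79A, TNFRSF13C, HLA-DRA, BACH2 and FCRLA were higher and CD79B and SYK lower (0.618). CD8A was the 1 gene higher of 4 T and NK cell markers (mean 0.91, 0.099), and 0 of 4 stromal and epithelial markers were called by limma (1 at unadjusted p below 0.05; 0.347). No myeloid or erythroid and megakaryocyte marker passed the value filter at 48 h. Genes named here because their count was 5 or fewer were chosen after their values were seen.

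**Figure D4:**
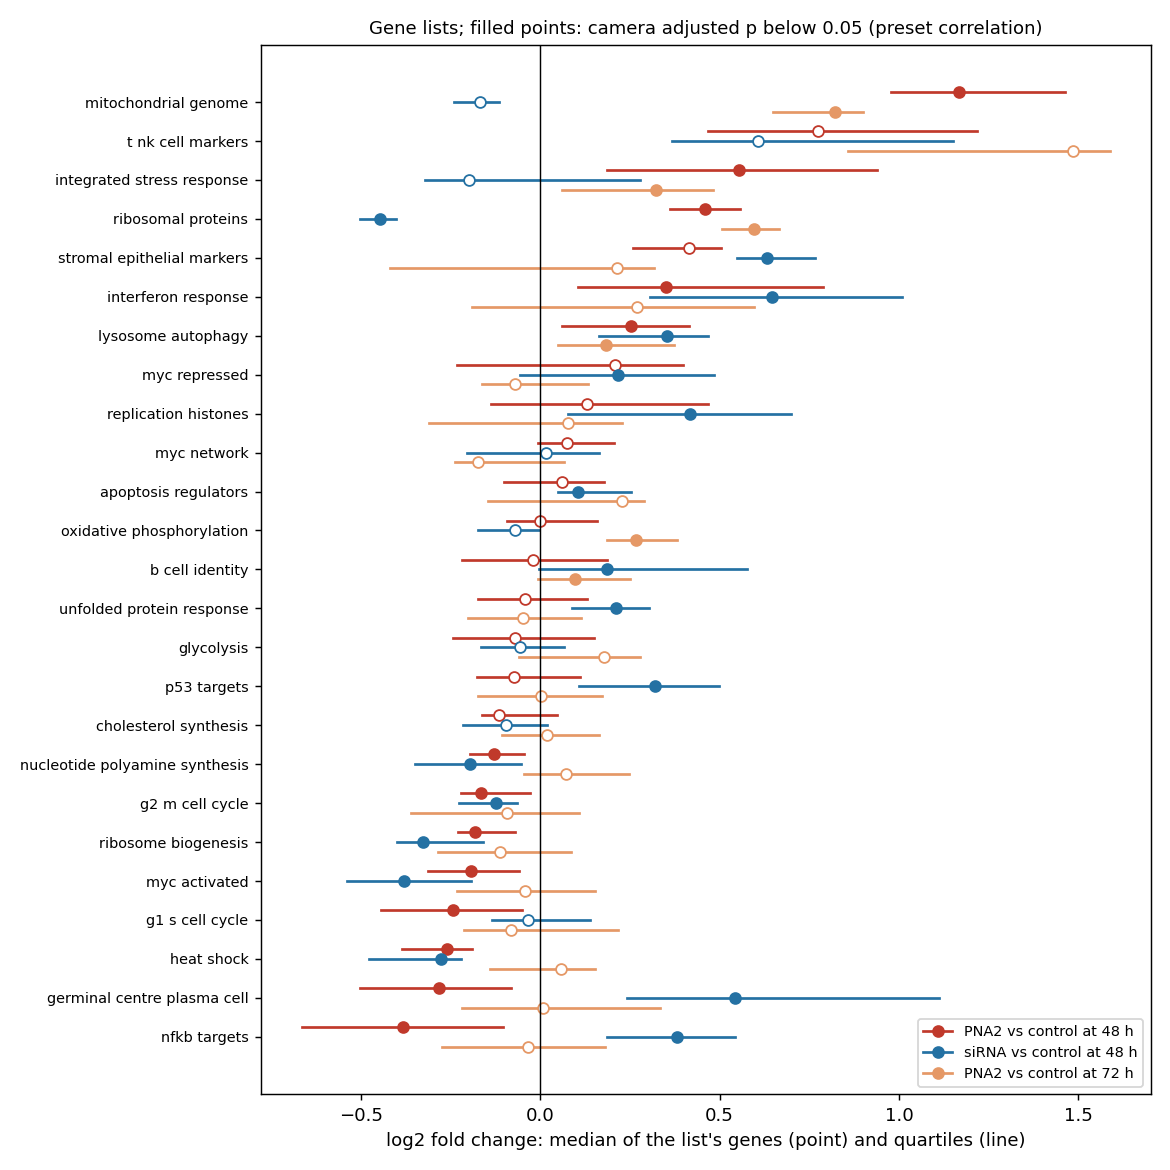
Median log2 fold change with quartiles of each gene list for PNA2 against control at 48 h (red), siRNA against control at 48 h (blue) and PNA2 against control at 72 h (orange), filled where camera with a preset correlation passed. The mitochondrial list has a mean of 1.29 at 48 h and 0.77 at 72 h in the libraries labelled PNA2, and -0.14 in siRNA, where it did not pass.

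In all, 2284 of 14136 genes differed between the libraries labelled PNA2 and the controls at 48 h (1147 higher, 1137 lower, 50.2% higher), 198 of them by a log2 change of 1 or more. Without rescaling for library totals the count was 2181 with 92.3% higher, because that scaling moved the median of all genes by 0.19, so changes are given relative to it. Within batch A alone 1847 genes differed and within batch B alone 1643, and 404 differed in both, 385 of them in one direction. Across 13060 genes the log2 changes of the batches had a Pearson correlation of 0.28, over genes that are not independent replicates.

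The comparison of siRNA with PBS at 48 h asked how transcripts differed after MYC siRNA, with MYC lower in all 4 libraries. MYC-activated genes and the ribosome were lower. Of 53 MYC-activated genes 28 were lower and 0 higher (36 adjusted over the list alone), with a mean log2 change of -0.34 (camera adjusted p = 1.55e-13, adjusted p = 0.221 with an estimated correlation; -0.39 within batch A). PPRC1, a coactivator of mitochondrial biogenesis, had deposited means of 1470 ± 113 (SD, n = 4) and 1950 ± 287 (n = 6). Its fitted log2 change was -0.69 (SE 0.08, adjusted p = 0.000115), and RRP12, of ribosome export, changed by -0.59 (SE 0.07, adjusted p = 0.000127). Ribosomal protein genes were lower in 59 of 67 cases and higher in 0 (63 lower adjusted over the list alone), with a mean of -0.44 (camera adjusted p = 1.27e-26, adjusted p = 0.178 with an estimated correlation; -0.43 within batch A). RPS24 changed by -0.65 (SE 0.10, adjusted p = 0.000996) and RPL27 by -0.50 (SE 0.08, adjusted p = 0.00136). Ribosome biogenesis genes were lower in 12 of 29 cases and higher in 0 (17 lower adjusted over the list alone), with a mean of -0.30 (camera adjusted p = 4.71e-07, adjusted p = 0.392 with an estimated correlation; -0.37 within batch A). The helicase DDX21 changed by -0.62 (SE 0.11, adjusted p = 0.00199) and POLR1B, of RNA polymerase I, by -0.56 (adjusted p = 0.00487). BOP1 (-0.4) and PES1 (-0.39), not matched by symbol and so not counted in these lists, were called lower too. When not rescaled, RRP12, RPS24, RPL27, DDX21 and POLR1B lost their calls (adjusted p 0.0652, 0.0777, 0.237, 0.0676 and 0.103).

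Further lists were lower in siRNA. Nucleotide and polyamine synthesis genes were lower in 6 of 23 cases and higher in 0 (9 lower adjusted over the list alone), with a mean log2 change of -0.20 (camera adjusted p = 0.00106, adjusted p = 0.547 with an estimated correlation). IMPDH2, of guanine nucleotide synthesis, changed by -0.48 (adjusted p = 0.00315) and PFAS by -0.59 (adjusted p = 0.00954; -0.51 and 0.0506 without control replicate 2). The G2/M list had 5 of 31 genes lower and 0 higher (5 adjusted over the list alone), namely CDC25B, BUB1, KIF11, CCNB1 and CDC20, with a mean of -0.14 (camera adjusted p = 0.00775, adjusted p = 0.598 with an estimated correlation). BUB1 changed by -0.46 (adjusted p = 0.00409) and CDC25B by -0.46 (adjusted p = 0.00868). IMPDH2 (-0.25, adjusted p = 0.226), PFAS (-0.35, 0.118), BUB1 (-0.23, 0.285) and CDC25B (-0.23, 0.27) lost their calls when not rescaled. With a replicate block CDC25B (0.0507) and PFAS (0.057) lost theirs. When not rescaled the nucleotide and G2/M means moved with the median of all genes (by 0.22) to 0.035 and 0.091. The G2/M call was lost there (camera adjusted p = 0.0715). Without control replicate 1 these means were -0.13 and -0.084, and within batch A -0.25 and -0.14. Of 13 heat shock genes 5 were lower and 0 higher (8 lower adjusted over the list alone), DNAJB1, BAG3, HSPA8, HSP90AB1 and HSPH1, with a mean of -0.33 (camera adjusted p = 6.96e-05, adjusted p = 0.178 with an estimated correlation; -0.32 within batch A). DNAJB1 changed by -0.52 (adjusted p = 0.0057) and HSPA8 by -0.49 (adjusted p = 0.00684). The HSPA8 call was lost under quantile normalization (-0.22, adjusted p = 0.0759) and with a replicate block (-0.41, 0.0629), and both calls were lost when not rescaled (DNAJB1 -0.28, adjusted p = 0.205; HSPA8 -0.25, 0.307). Their adjusted p ran over the alternatives from 0.000612 to 0.273 for DNAJB1 and from 0.000678 to 0.395 for HSPA8. Over the alternatives the adjusted p of PFAS ran from 2.49e-06 to 0.118.

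Immune and differentiation genes were higher in siRNA. Interferon-induced genes were higher in 15 of 27 cases and lower in 1, MX2 (16 and 1 adjusted over the list alone), with a mean log2 change of 0.79 (camera adjusted p = 3.5e-09, adjusted p = 0.178 with an estimated correlation; 0.96 within batch A). BST2, which tethers viruses, rose to 1030 ± 122 (SD, n = 4) from 605 ± 154 (n = 6), a log2 change of 0.74 (SE 0.12, adjusted p = 0.00124). Germinal centre and plasma cell genes were higher in 10 of 22 cases and lower in 0 (15 higher adjusted over the list alone), with a mean of 0.69 (camera adjusted p = 1.56e-07, adjusted p = 0.178 with an estimated correlation; 0.74 within batch A). RGS13, a regulator of B cell chemotaxis, rose to 3340 ± 557 (SD, n = 4) from 1650 ± 482 (n = 6), a log2 change of 1.23 (SE 0.17, adjusted p = 0.000535). PRDM1, the plasma cell transcription factor, rose by 1.80 (SE 0.28, adjusted p = 0.000948; 1.32 with the batches aligned on their controls). NF-kB targets were higher in 8 of 22 cases and lower in 0 (10 higher adjusted over the list alone), with a mean of 0.41 (camera adjusted p = 6.48e-06, adjusted p = 0.178 with an estimated correlation; 0.40 within batch A). ICAM1 rose by 0.91 (SE 0.14, adjusted p = 0.00101) and JUNB, an AP-1 factor, by 0.41 (adjusted p = 0.00274).

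B cell identity genes were higher in 9 of 28 cases in siRNA and lower in 0 (9 higher adjusted over the list alone), with a mean of 0.32 (camera adjusted p = 0.000839, adjusted p = 0.479 with an estimated correlation; 0.29 within batch A). CD72, a B cell coreceptor, changed by 0.95 (SE 0.14, adjusted p = 0.000617) and POU2F2 by 0.74 (adjusted p = 0.0013). Lysosome and autophagy genes were higher in 8 of 27 cases and lower in 0 (8 higher adjusted over the list alone), with a mean of 0.32 (camera adjusted p = 2.26e-05, adjusted p = 0.392 with an estimated correlation; 0.45 within batch A). Subunits of the proton pump were among them, ATP6V0D1 (0.49, adjusted p = 0.000996) and ATP6V1H (0.57, adjusted p = 0.00144). Of 17 MYC-repressed genes 5 were higher and 0 lower (6 adjusted over the list alone), TP53INP1, SESN3, GADD45B, TXNIP and BTG2, with a mean of 0.25 (camera adjusted p = 0.00332, adjusted p = 0.217 with an estimated correlation; 0.41 within batch A). TP53INP1, a stress gene, changed by 0.62 (SE 0.10, adjusted p = 0.00087) and TXNIP by 0.43 (adjusted p = 0.00429).

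Genes of p53 and cell death moved in siRNA too. Of 18 p53 targets 7 were higher, and TRIAP1 and TIGAR lower (9 and 2 adjusted over the list alone), with a mean of 0.31 (camera adjusted p = 0.00122, adjusted p = 0.125 with an estimated correlation; 0.33 within batch A). The death receptor FAS changed by 0.69 (adjusted p = 0.00388) and ZMAT3 by 0.42 (adjusted p = 0.00223). Of 24 apoptosis regulators 6 were higher and 1, BAK1, lower (6 and 1 adjusted over the list alone), with a mean of 0.16 (camera adjusted p = 0.0135, adjusted p = 0.178 with an estimated correlation; 0.22 within batch A). MCL1, which blocks cell death, rose to 47400 ± 6590 (SD, n = 4) from 29800 ± 5060 (n = 6), a log2 change of 0.69 (SE 0.17, adjusted p = 0.0115), and CASP8 changed by 0.39 (adjusted p = 0.00928). Of 20 replication histones 3 were higher and 0 lower (1 adjusted over the list alone), H2AC8, H1-2 and H2BC11, with a mean of 0.42 (camera adjusted p = 0.00436, adjusted p = 0.178 with an estimated correlation; 0.60 within batch A). H1-2 changed by 1.09 (SE 0.12, adjusted p = 0.000115) and H2BC11 by 0.72 (adjusted p = 0.0394). The histone list's call was lost when not rescaled (0.64, camera adjusted p = 0.0703) and also without the batch term (0.495, 0.219). Over the alternatives the list's camera adjusted p ran from 0.000669 to 0.219.

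Unfolded protein response genes had a mean of 0.19 in siRNA (camera adjusted p = 0.00332, adjusted p = 0.547 with an estimated correlation; 0.32 within batch A), with 2 of 21 higher and 0 lower (0 adjusted over the list alone), the transcription factor XBP1 (0.42, adjusted p = 0.0368) and SDF2L1 (0.28, adjusted p = 0.0351). The stromal and epithelial list had a mean of 0.68 (camera adjusted p = 0.033, adjusted p = 0.221 with an estimated correlation; 0.50 within batch A), with FN1 the 1 gene higher of 4 (1.17, adjusted p = 0.0166), 3 adjusted over the list alone, and PECAM1 not called (0.63, adjusted p = 0.072). The list's call was lost without control replicate 4 (0.77, camera adjusted p = 0.0711) and within batch A (camera adjusted p = 0.0759), and over the alternatives its adjusted p ran from 0.0168 to 0.111. The FN1 call was lost without control replicate 1 (adjusted p = 0.0568). XBP1, SDF2L1 and H2BC11 each lost their call without control replicate 1 (adjusted p 0.106, 0.0844 and 0.0792) or 2 (0.116, 0.0808 and 0.0651) and without siRNA replicate 1 (0.1, 0.0706 and 0.0668), 2 (0.0795, 0.0558 and 0.0518), 3 (0.0623, 0.0984 and 0.0908) or 4 (0.0717, 0.0809 and 0.12). Without control replicate 4 the calls of XBP1 (0.0583) and H2BC11 (0.057) were lost. Over the alternatives the adjusted p ran from 9.66e-06 to 0.135 for XBP1, 0.000709 to 0.0984 for SDF2L1, 0.00324 to 0.188 for H2BC11 and 0.000691 to 0.0755 for FN1.

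Among the largest increases in siRNA were genes with far lower control values in batch A than in batch B. SOCS3, a feedback inhibitor of cytokine receptors, stood at 200 ± 26.5 (SD, n = 4) against 40.9 ± 57.1 (n = 6), a log2 change of 6.32 (SE 0.64, adjusted p = 8.14e-05). The control mean of SOCS3 was -10.2 in batch A and 92 in batch B, so the size of the change depends on the deposited batch adjustment, and it was 3.12 with the batches aligned on their controls. The kinase SGK1 changed by 5.07 (SE 0.87, adjusted p = 0.00165; 2.38 aligned), neuroglobin NGB by 4.83 (SE 0.80, adjusted p = 0.00136; 1.94 aligned) and the cytokine IL10 by 4.56 (SE 1.03, adjusted p = 0.00793; 2.28 aligned). The lipid antigen receptor CD1C changed by 3.23 (SE 0.46, adjusted p = 0.00055; 2.00 aligned). All 5 lost their call without the batch term, SOCS3 with 3.66 (adjusted p = 0.123, range over the alternatives 1.06e-07 to 0.123). Of 46 genes picked by the naming rule in this comparison 13 lost their call that way, PRDM1 (adjusted p = 0.0577, range 2.4e-05 to 0.0577), ICAM1 (0.107, range 8.62e-06 to 0.107) and MCL1 (0.124) among them.

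Among the largest decreases in siRNA was C11orf54, a predicted ester hydrolase, at 870 ± 89.8 (SD, n = 4) against 1430 ± 294 (n = 6), a log2 change of -1.06 (SE 0.12, adjusted p = 0.000123; -1.25 aligned on the controls). AMN changed by -1.19 (SE 0.17, adjusted p = 0.000509), the synaptic genes CPLX1 by -1.21 (SE 0.22, adjusted p = 0.00222) and LRFN4 by -1.07 (SE 0.14, adjusted p = 0.000396), and LONRF2, a ubiquitin ligase, by -1.05 (SE 0.20, adjusted p = 0.0032). RPS10P3, a pseudogene that shares reads with RPS10, changed by -1.02 and is uncertain. In all, 2437 of 14136 genes differed in siRNA (1233 higher, 1204 lower, 50.6% higher), 391 of them by a log2 change of 1 or more (357 higher, 34 lower). Without rescaling the count was 2198 with 96.6% higher, since the median of all genes moved by 0.22. Within batch A 2325 genes differed. The count was 1438 without control replicate 1, 1176 without control replicate 2, and 1499, 1489 and 1414 without siRNA replicates 1, 2 and 4. The other lists tested in siRNA, mitochondrial transcripts among them (0 of 13 called by limma and 0 at unadjusted p below 0.05, mean -0.14, camera adjusted p = 0.306), did not pass. Of 4 T and NK cell markers 1, CD8A, was higher (mean 0.91, camera adjusted p = 0.0723). In the integrated stress response list SHMT2 alone was lower, and the list's median of -0.20 and mean of 0.15 differed in sign (camera adjusted p = 0.382). The mitochondrial share was 2.24% ± 0.129 (SD, n = 4), not different from the controls (exact two-sided permutation p = 0.581).

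The direct comparison of PNA2 with siRNA cannot separate the reagents' effects from that of siRNA electroporation. MYC was higher in the libraries labelled PNA2 than in siRNA by 1.06 (SE 0.12, adjusted p = 3.27e-05; 0.90 within batch A; exact two-sided permutation p = 0.0286 over 70 arrangements, the smallest possible). Ribosomal protein genes were higher in 65 of 67 cases and lower in 0 (65 higher adjusted over the list alone), with a mean log2 difference of 0.88 (camera adjusted p = 3.73e-48, adjusted p = 0.116 with an estimated correlation; 0.82 within batch A). RPL27 differed by 1.17 (SE 0.09, adjusted p = 2.51e-06) and RPL34 by 1.22 (adjusted p = 4.92e-06). Mitochondrial transcripts were higher in 11 of 13 cases and lower in 0 (12 higher adjusted over the list alone), with a mean of 1.44 (camera adjusted p = 2.91e-09, adjusted p = 0.318 with an estimated correlation; 1.32 within batch A). MT-ND1 differed by 1.90 (SE 0.26, adjusted p = 0.000122) and MT-ND2 by 1.77 (SE 0.18, adjusted p = 1.58e-05).

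Germinal centre and plasma cell genes were lower in the libraries labelled PNA2 than in siRNA in 18 of 22 cases and higher in 0 (19 lower adjusted over the list alone), with a mean of -0.97 (camera adjusted p = 5.03e-10, adjusted p = 0.138 with an estimated correlation; -0.97 within batch A). IRF4 stood at 6500 ± 744 against 10500 ± 1250 (SD, n = 4 each), a log2 difference of -0.76 (SE 0.08, adjusted p = 2.72e-05), and RGS13 differed by -1.51 (SE 0.19, adjusted p = 6.28e-05). NF-kB targets were lower in 16 of 22 cases and higher in 0 (17 lower adjusted over the list alone), with a mean of -0.71 (camera adjusted p = 9.99e-10, adjusted p = 0.116 with an estimated correlation; -0.80 within batch A). ICAM1 differed by -1.67 (SE 0.15, adjusted p = 7.62e-06) and CFLAR, which blocks death receptor signalling, by -0.91 (adjusted p = 0.000171). Of 18 p53 targets 8 were lower and 1, TRIAP1, higher (9 and 1 adjusted over the list alone), with a mean of -0.31 (camera adjusted p = 0.00681, adjusted p = 0.116 with an estimated correlation; -0.35 within batch A). FAS differed by -0.87 (SE 0.15, adjusted p = 0.000676) and DDB2, of DNA repair, by -0.70 (adjusted p = 0.00373; -0.42 without PNA2 replicate 2).

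Other differences between the groups were less steady. MYC-activated genes were higher in 18 of 53 cases and lower in DUSP2 and GNL3 (20 and 3 adjusted over the list alone), with a mean of 0.15 (camera adjusted p = 0.0023, adjusted p = 0.755 with an estimated correlation). The mean was 0.005 within batch A and did not pass (camera adjusted p = 0.296), nor with only the 2 groups compared (0.005, camera adjusted p = 0.297, range over the alternatives 2.99e-10 to 0.297). It was 0.30 without PNA2 replicate 2 and 0.095 without PNA2 replicate 4. PPRC1 differed by 0.50 (adjusted p = 0.000747) and SORD, of sorbitol metabolism, by 0.81 (SE 0.14, adjusted p = 0.000864). Unfolded protein response genes were lower in 7 of 21 cases and higher in 0 (8 lower adjusted over the list alone), with a mean of -0.20 (camera adjusted p = 0.00407, adjusted p = 0.755 with an estimated correlation), -0.077 within batch A, -0.15 without PNA2 replicate 1 (camera adjusted p = 0.0617) and -0.43 without PNA2 replicate 2. SDF2L1 differed by -0.47 (adjusted p = 0.00233) and PDIA6 by -0.34 (adjusted p = 0.00552). Interferon-induced genes were lower in 8 of 27 cases, and IFIT5 and MX2 were higher (10 and 3 adjusted over the list alone). Their mean was -0.36 (camera adjusted p = 0.0178, adjusted p = 0.755 with an estimated correlation), -0.25 within batch A (camera adjusted p = 0.337), -0.35 without PNA2 replicate 1 (0.142), -0.59 without replicate 2 and -0.33 without replicate 3 (0.0633). IFIH1, an RNA sensor, differed by -0.99 (SE 0.12, adjusted p = 4.6e-05). Over the alternatives the camera adjusted p ran from 1.46e-11 to 0.297 for the unfolded protein response and from 1.71e-05 to 0.337 for interferon.

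The integrated stress response list was higher in the libraries labelled PNA2 than in siRNA, with 7 of 24 genes higher and 0 lower (9 adjusted over the list alone) and a mean of 0.54 (camera adjusted p = 0.00214, adjusted p = 0.755 with an estimated correlation). The mean was -0.22 without PNA2 replicate 2 (camera adjusted p = 0.927) and 0.96 within batch A. SHMT2, of one-carbon metabolism, differed by 0.56 (adjusted p = 0.00148) and CEBPB, a stress and inflammation factor, by 1.99 (SE 0.49, adjusted p = 0.00776; 0.96 without PNA2 replicate 2). The G1/S list had 8 of 30 genes lower, and CCND2 and E2F3 higher (8 and 2 adjusted over the list alone), with a mean of -0.21 (camera adjusted p = 0.0178, adjusted p = 0.775 with an estimated correlation). It was 0.045 without PNA2 replicate 2, -0.38 without replicate 1 and -0.35 within batch A. CCND3 differed by -0.56 (adjusted p = 0.0021) and E2F1 by -0.64 (adjusted p = 0.00829; -0.36 without PNA2 replicate 2). B cell identity genes were lower in 10 of 28 cases and higher in FCRLA, HLA-DRA, TNFRSF13C and BTK (10 and 4 adjusted over the list alone), with a mean of -0.34 (camera adjusted p = 0.0273, adjusted p = 0.755 with an estimated correlation). It was -0.064 without PNA2 replicate 2 (camera adjusted p = 0.927), -0.54 without replicate 1 and -0.46 within batch A. CD79B, of the B cell receptor, differed by -0.86 (adjusted p = 0.000344) and CD72 by -0.79 (adjusted p = 0.00149). The CD72 call was lost without the batch term (-0.52, adjusted p = 0.0732) and also not rescaled (-0.54, 0.128), with a range over the alternatives of 0.000294 to 0.128. Over the alternatives the camera adjusted p reached from 7.72e-07 to 0.927 for the stress response, 0.000112 to 0.756 for G1/S and 0.000441 to 0.927 for B cell identity.

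Of single genes, ANK2, encoding a membrane anchor, stood at 146 ± 70.3 in the libraries labelled PNA2 against 34.6 ± 4.7 in siRNA (SD, n = 4 each), a log2 difference of 1.99 (SE 0.30, adjusted p = 0.000313), and SNORD3A differed by 5.66 (SE 1.04, adjusted p = 0.00127). TM6SF1 differed by 1.76 (SE 0.44, adjusted p = 0.0097) and by 0.97 without PNA2 replicate 2. SGK1, SOCS3 and NGB differed by -6.56, -6.31 and -4.86, and by -2.78, -2.96 and -2.66 with the batches aligned on their controls, and they lost their call without the batch term (adjusted p 0.0728, 0.12 and 0.149). CUEDC1 (-4.10), the transcription factor CREB3L1 (-3.99) and the somatostatin receptor SSTR2 (-3.88, adjusted p = 0.0306) differed by -2.73, -2.55 and -1.18 without PNA2 replicate 2. The SSTR2 call was lost without siRNA replicate 1 (adjusted p = 0.0572), 2 (0.0633), 3 (0.0581) or 4 (0.0597), and its adjusted p ran over the alternatives from 0.000106 to 0.097. In all 3325 of 14136 genes differed between the groups (1702 higher and 1623 lower in PNA2, 51.2% higher). Without rescaling the count was 1785 with 39.2% higher. Within batch A 3049 genes differed.

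The calls of both reagents against the same 6 controls overlapped in 172 genes that were higher and 217 that were lower, and 227 had opposite calls. Independent lists of those sizes would share 100, 97 and 197 genes. Unchanged groups simulated against those controls shared 0.01, 0.02 and 0 on average over 100 draws. Groups without an effect give few calls, so these counts cannot show how much overlap the shared controls add among called genes. With the controls split so that each reagent had its own, the median over 18 splits was 45.5 genes shared higher (28 to 68), 72.5 shared lower (43 to 105) and 67.5 opposite (19 to 227). Across 14136 genes the log2 changes had a Pearson correlation of 0.17, against 0.35 in the simulation and a median of 0.05 with split controls. Their covariance was 0.0312 against 0.0165 simulated and 0.00996 with split controls (-0.0231 to 0.0424). The shared count was 200 without control replicate 1 and 179 without control replicate 2, from 389.

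The comparison of PNA2 with PBS at 72 h asked the same of the later time. Mitochondrial transcripts were again higher, at 7.29% ± 1.02 (SD, n = 5) of the totals in PNA2 against 4.35% ± 0.32 (n = 5), with no overlap (exact two-sided permutation p = 0.00794 over 252 arrangements, adjusted over 3 comparisons p = 0.0119). All 13 mitochondrial genes were higher (13 adjusted over the list alone), with a mean log2 change of 0.77 (camera adjusted p = 5.69e-12, adjusted p = 0.328 with an estimated correlation). MT-ND2 rose to 56400 ± 8160 (SD, n = 5) from 25900 ± 2040 (n = 5), a log2 change of 1.11 (SE 0.10, adjusted p = 8.73e-05), and MT-ATP6 by 0.86 (SE 0.09, adjusted p = 0.000185). MT-CO1, of complex IV, changed by 0.88 (SE 0.08, adjusted p = 0.000141), but by -0.07 under quantile normalization, which gives equal ranks equal values in all libraries. Ribosomal protein genes were higher in 65 of 68 cases and lower in 0 (67 higher adjusted over the list alone), with a mean of 0.59 (camera adjusted p = 7.35e-34, adjusted p = 0.328 with an estimated correlation). RPS15A changed by 0.88 (SE 0.10, adjusted p = 0.00045), RPS6 by 0.59 (SE 0.08, adjusted p = 0.000714; 0.11 and not called under quantile normalization) and RPL4 by 0.55 (SE 0.07, adjusted p = 0.000714).

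Nuclear genes of the respiratory chain were higher at 72 h, in 16 of 31 cases with 0 lower (20 higher adjusted over the list alone), and a mean of 0.29 (camera adjusted p = 3.04e-08, adjusted p = 0.328 with an estimated correlation). UQCRFS1 and UQCRC1, of complex III, changed by 0.54 (SE 0.08, adjusted p = 0.00131) and 0.41 (SE 0.07, adjusted p = 0.00286), and COX5A, of complex IV, by 0.46 (SE 0.09, adjusted p = 0.00426). Across 11966 genes the log2 changes at 72 h had a Spearman correlation of -0.26 with transcript length. With that trend removed all 6 lists called at 72 h, this one among them, kept their call. Integrated stress response genes were higher in 13 of 24 cases and lower in 0 (17 and 1 adjusted over the list alone), with a mean of 0.27 (camera adjusted p = 0.000109, adjusted p = 0.103 with an estimated correlation). TRIB3, a stress-induced pseudokinase, rose to 1060 ± 127 (SD, n = 5) from 654 ± 32.8 (n = 5), a log2 change of 0.68 (SE 0.09, adjusted p = 0.000802), DDIT4 by 0.56 (SE 0.08, adjusted p = 0.00131) and CEBPB by 0.51 (SE 0.10, adjusted p = 0.00477). Lysosome and autophagy genes were higher in 10 of 27 cases and lower in 0 (11 higher adjusted over the list alone), with a mean of 0.22 (camera adjusted p = 0.00099, adjusted p = 0.347 with an estimated correlation). PSAP changed by 0.62 (SE 0.06, adjusted p = 0.000153), the cholesterol transporter NPC2 by 0.75 (SE 0.11, adjusted p = 0.00131) and CTSZ by 0.41 (adjusted p = 0.00305).

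B cell identity genes at 72 h were higher in 9 of 28 cases, and CIITA and MS4A1 were lower (10 and 2 adjusted over the list alone), with a mean of 0.13 (camera adjusted p = 0.0262, adjusted p = 0.347 with an estimated correlation). The list's call was lost without PNA2 replicate 1 (0.12, camera adjusted p = 0.0544) and under quantile normalization (0.074), and over the alternatives its adjusted p ran from 0.0158 to 0.36. CD79A, of the B cell receptor, rose to 11300 ± 1580 (SD, n = 5) from 6620 ± 361 (n = 5), a log2 change of 0.77 (SE 0.09, adjusted p = 0.00048), VPREB3 by 0.91 (SE 0.14, adjusted p = 0.00152) and FCRLA by 0.45 (SE 0.07, adjusted p = 0.00156). The other lists tested did not pass, among them MYC-activated genes, with 9 of 54 lower and RABEPK, AIMP2 and SLC19A1 higher (camera adjusted p = 0.717). Glycolysis had 4 of 18 genes higher, GAPDH, ENO1, PGAM1 and ALDOC (camera adjusted p = 0.0885). Of 3 T and NK cell markers 1, LCK, was higher (mean 1.14, camera adjusted p = 0.187). Of 3 myeloid markers 0 were called by limma and 1 had an unadjusted p below 0.05 (camera adjusted p = 0.915), and no erythroid and megakaryocyte marker passed the value filter.

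Among single genes with the largest increases at 72 h were the matrix protein gene FMOD, at 116 ± 17.2 (SD, n = 5) against 53.4 ± 12 (n = 5), a log2 change of 1.12 (SE 0.18, adjusted p = 0.00203), and the tubulin gene TUBA1A (1.09, SE 0.21, adjusted p = 0.00408). The small heat shock gene HSPB1 changed by 1.08 (SE 0.16, adjusted p = 0.00131), IGFBP4, which binds insulin-like growth factors, by 1.07 (SE 0.11, adjusted p = 0.000225) and JUP, a junction protein, by 1.06 (SE 0.14, adjusted p = 0.000714). Among the largest decreases were YJEFN3, at 64.9 ± 54.3 against 299 ± 61.8 (SD, n = 5 each), a log2 change of -2.56 (SE 0.48, adjusted p = 0.00377), and C1orf27 (-1.32, SE 0.28, adjusted p = 0.00738). GOLGA8A (-1.33, SE 0.10, adjusted p = 3.37e-05), GOLGA8B (-1.30, SE 0.12, adjusted p = 0.000114) and GOLGA6L9 (-1.38, SE 0.21, adjusted p = 0.00151) belong to golgin families with near-identical copies and are uncertain one by one. NKTR, a cyclophilin-related gene, changed by -1.81 (SE 0.54, adjusted p = 0.0304). Its call was lost without control replicate 1 (adjusted p = 0.058), 3 (0.057), 4 (0.0625) or 5 (0.0555) and without PNA2 replicate 1 (-1.57, 0.0731), with a range over the alternatives of 0.0127 to 0.0731. In all, 2849 of 11985 genes differed at 72 h (1448 higher, 1401 lower, 50.8% higher), 131 of them by a log2 change of 1 or more. On the recovered reads edgeR called 2837 and DESeq2 3342.

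Between the times, 352 genes were higher at both and 329 lower at both, of 11341 genes tested at both, where independent lists would share 130 and 117. Fisher's exact two-sided p was 2.81e-81 and 4.03e-79 over genes, which are not independent replicates, and 46 genes had opposite calls. The log2 changes at 48 h and 72 h had a Pearson correlation of 0.33 and a Spearman correlation of 0.32 across genes, and those of siRNA at 48 h and PNA2 at 72 h had a Pearson correlation of 0.10.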

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

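All tests of explanations in this part were chosen after the results were seen. The rules that single out a library or a difference, and the counts over other splits of the libraries, were fixed before the data were examined.

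A library far from the rest of its group was found in 11 of 182 groups of values tested, and chance alone gives about 1 in 20. In mean log2 value over a list, PNA2 48 h replicate 2 stood apart for the integrated stress response at 10.9 (others 8.97 to 9.05), nucleotide synthesis at 10.48 (11.04 to 11.1), MYC-repressed genes at 9.01 (8.42 to 8.48) and the unfolded protein response at 11.74 (11.17 to 11.19). In the same library LTB and SSTR2 lay at 0 (others 5.16 to 5.36 and 6.38 to 7.19). Control 48 h replicate 3 stood apart for mitochondrial genes at 12.43 (13.73 to 14.46), siRNA replicate 3 for lysosome genes at 9.5 (9.43 to 9.44), and siRNA replicate 1 for apoptosis regulators at 9.95 (9.91 to 9.92) and CREB3L1 at 6.25 (6.79 to 6.87). At 72 h MYC in PNA2 replicate 3 lay at 8.85 on the log2 scale, against 10.82 to 10.99 in the other 4. Of 83 effects compared between the times, 2 went opposite ways in every library: ASB13, with -0.69 at 48 h and 0.37 at 72 h, and UQCRC1, with -0.28 and 0.41. The difference between the times was not tested.

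Mitochondrial and ribosomal protein transcripts were higher in the libraries labelled PNA2 at both times. Length bias as the whole cause is argued against, since after removal of the trend with transcript length the ribosomal protein mean was 0.42 at 48 h and 0.49 at 72 h, although at 72 h genes matched in length and level had a median of 0.23 beside 0.60 for the list. A difference between batches is argued against by the lowest within-batch mean of both lists, 0.39. More RNA without poly(A) tails could raise mitochondrial transcripts and would raise replication histones as well, whose higher median was 0.13 beside mitochondrial medians of 1.17 and 0.82, which argues against it as the whole cause. MT-RNR2 (1.63) and the small nucleolar RNA SNORD3A (5.85) at 48 h go with it, while of 8 small nucleolar RNAs tested 1 was higher and 2 were lower (median -0.46). A response to PNA2 treatment stays open and was not tested, and so do technical causes without a test here, such as RNA quality.

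MYC was not lower in the libraries labelled PNA2 at 48 h. A swap between a control and a PNA2 library is argued against by the mitochondrial share, in which 0 libraries of either group lay within the range of the other. The authors' batch adjustment is argued against by the lower 95% bounds within batches, the lower of which was -0.18, short of 0.5 times the siRNA change of -0.82. Scaling is argued against by the lowest change over the scalings, 0.24. An effect of PNA2 on protein rather than transcript stays open and was not tested.

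Other splits of the libraries into groups of the same sizes gave as many changed genes, the real split included, in 2 of 100 for PNA2 against control at 48 h, 1 of 100 for siRNA against control, 1 of 35 for PNA2 against siRNA and 1 of 100 for 72 h. The other split for PNA2 at 48 h joined controls 1, 2 and 4 and PNA2 replicate 1, all of batch A, with 4064 genes. With the batch term it set them against the remaining batch A library of these groups, PNA2 replicate 2, so it points to that library, whose median correlation with its group was 0.9705 (0.9874 or more in the others). Within batches the PNA2 counts were 1847 and 1643.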

How the results depend on the processing

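Results without a batch term, as the design was first written, with aligned batches, within batches and with the length trend removed were tests chosen after the data were seen, and the others before the data were examined. Genes called in the 4 comparisons (2284, 2437, 3325 and 2849 in the order PNA2 at 48 h, siRNA, PNA2 against siRNA, 72 h) moved to 198, 391, 696 and 131 with a log2 minimum of 1, which removes genes by construction. A replicate block gave 848, 956 and 1819 at 48 h and 2769 at 72 h, with fewer libraries at 48 h. Replicate numbers gave no clear pairing: same-number correlations ran from -0.35 to 0.11, and only 1 exceeded 0.1. At 72 h they were 0.11 in replicate 4 and 0.1 in replicate 2, against a median of -0.01 in other pairs. Pairing was therefore not excluded. Fitting only the 2 groups compared gave 1010 for PNA2 and 4563 for siRNA. Not rescaled, PNA2 against siRNA gave 1785. Without a batch term siRNA gave 1184, and also not rescaled 1395, with 1195 for PNA2 against siRNA. Leaving out 1 library gave 1691 to 3032, 1176 to 2522, 2499 to 3915 and 2086 to 3333. The MYC change in PNA2 at 48 h, 0.24 and not called, was called when not rescaled (0.44), under quantile normalization (0.26), with no batch term and not rescaled (0.44), within batch B (0.47) and without PNA2 replicate 2 (0.29), and ran from 0.15 to 0.29 with 1 library left out. In siRNA it ran from -0.91 to -0.59 and was called in all 24 alternatives. At 72 h it ran from -0.43 to 0.24 with 1 library left out and was called in 0 of 21. All 47 list calls of camera were lost with an estimated correlation (0 called, 12 list tests at unadjusted p below 0.05). Within batch B 4 list means in PNA2 reversed, MYC-activated 0.011, ribosome biogenesis 0.093, nucleotide synthesis 0.051 and integrated stress response -0.049, and the lysosome mean fell to 0.006. With 1 library left out the nucleotide mean in PNA2 ran from -0.227 to 0.009, and the G1/S mean in PNA2 against siRNA from -0.377 to 0.045. MT-CO1 at 72 h was -0.07 under quantile normalization. Calls shared by PNA2 and siRNA (389) were 242 with no filter, 94 with the block and 179 to 406 with 1 library left out. Calls shared by 48 h and 72 h (681) were 380 with the block, 375 with only 2 groups and 541 to 791 with 1 library left out. Of values of named genes with 1 library left out, 344 of 370, 438 of 460, 252 of 256 and 285 of 290 kept direction and side of the threshold, and of list values 121 of 130, 169 of 170, 82 of 88 and 59 of 60. Of 37, 46 and 32 genes picked by the naming rule at 48 h (PNA2, siRNA, PNA2 against siRNA), calls were lost in 2, 13 and 5 without the batch term, 10, 18 and 7 also not rescaled, 7, 11 and 1 not rescaled, 6, 10 and 2 with the block, and 6, 0 and 0 with only 2 groups. Except where given, the cause was not tested. Whole reads could not be recovered at 48 h, so edgeR and DESeq2 were not run there. Depth limits genes below a value of 10, which were not tested.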

Other observations

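The test of retained introns in this part, and the genes named in it, were chosen after the results were seen. Genes lower at both times in the libraries labelled PNA2 included the following. SRSF10 changed by -0.49 at 48 h and -1.17 at 72 h, PNN by -0.50 and -0.94, ARGLU1 by -0.48 and -0.95, LUC7L3 by -0.28 and -0.86, CCNL2 by -0.37 and -0.89, ZRANB2 by -0.32 and -0.96 and PRPF38B by -0.46 and -0.92. The decrease was not particular to PNA2 in all of them. PNN (-0.54), LUC7L3 (-0.37), CCNL2 (-0.29) and PRPF38B (-0.34) were called lower in siRNA at 48 h as well. SRSF10, ARGLU1 and ZRANB2 were not among the calls shared by both reagents. Among other genes called at both times were the chemokine CCL22 (-0.90 and -1.13), TPT1, a translation-related protein (0.38 and 0.92), the elongation factor EEF1A2 (1.63 and 1.24) and the transcription factor TBX21 (0.88 and 1.02).

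A hypothesis drawn after these values were seen was that genes with many annotated retained introns, as a set, were lower in the libraries labelled PNA2. Genes with 5 or more annotated retained-intron transcripts had a median log2 change of -0.058 at 48 h (1483 genes) and -0.058 at 72 h (1508 genes), without 1 of the genes above that has as many. Genes matched in length and level had medians of -0.006 and 0.035. The differences were -0.052 and -0.093, and over matched sets drawn at random 95% lay from -0.062 to -0.036 and from -0.118 to -0.077. The bound, also chosen after the results were seen, was -0.05 at both times, and the spread at 48 h includes it, so the test leaves the hypothesis open. Gene totals do not show whether introns were retained, and the cause was not tested.

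In PNA2 48 h replicate 2 all 24 integrated stress response genes lay above every control and every other PNA2 library, with a mean difference from the controls of 2.1 on the log2 scale against 0.22 in the other PNA2 libraries. DDIT3 stood at 10.31 (other PNA2 6.71 to 7.32, controls 5.56 to 7.24), ATF3 at 9.26 (3.91 to 4.69, 0 to 4.1) and CHAC1 at 9.09 (6.09 to 6.19, 4.9 to 6.68). Lysosome genes lay above in 23 of 27 cases, and ribosome biogenesis genes below in 25 of 29, G1/S genes in 24 of 30 and nucleotide synthesis genes in 21 of 23.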
